A study of Mus musculus with 9 samples.

How the data were processed

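The study compared RNA of epididymal fat between 5 mice transgenic for the tropomyosin Tm5NM1 and 4 wild-type mice, with 1 array per mouse. Per the labels' protocols, RNA was extracted with Trizol and cleaned on RNeasy columns with a DNase step, RNA integrity scores were above 7.8, and cRNA carrying biotin was prepared by an Ambion kit (MessageAmp). Scanning, image software and any normalization by the authors are not given in the sources used here. The mice are separate animals by their numbers; cage, litter, slide and array position are not given in the sources used here, so a slide effect was not tested.

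2 tables of probe values were used, both deposited for all 9 arrays and 45281 probes. The deposited values of the series matrix are intensities on a linear scale, with no stated normalization; array medians differed, so they were not quantile normalized. The deposited table called non-normalized gives an intensity and a detection p-value for each probe and array; per the file headers, the p-value is Illumina's detection p. Within an array a detection p cannot rise with the signal it was computed from. Ordered by the series matrix values, the detection p rose at no more than 1 place on any array. Ordered by the intensities of the table called non-normalized, it rose at 12137 to 12861 places on 8 of the 9 arrays. On these 8 arrays the table's intensity divided by the series matrix value ranged from 0.800 to 0.950 in whole thousandths, at 100% of probes to within the rounding of the files. These ratios were spread evenly, took 151 distinct values, and were unrelated between arrays (largest absolute r 0.00997 over 28 pairs) and to the level (largest absolute rho 0.0103). For transgenic mouse 147 the 2 tables were identical. How this difference arose is not given in the sources used here.

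The design fixed before the data were examined named the table called non-normalized. Because the detection p-values follow the series matrix values and not that table, the same steps were run on the series matrix values, a decision taken from this check before any comparison of the groups. The analysis on the table called non-normalized is given as an alternative. On the 8 arrays whose 2 tables differed, the ratios add a spread of 0.072 (mean SD within an array, log2). For transgenic mouse 147 they add none.

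Intensities were background-corrected and normalized with neqc in limma 3.58.1 (R 4.3.3), which takes the moments of the negative controls from the detection p-values, adds an offset of 16, normalizes by quantiles and takes log2. Probes with a detection p under 0.05 on at least 4 arrays were kept, 23354 in number, and 21927 were left out. Each probe was fitted with lmFit and eBayes, transgenic against wild type with no covariate, and p-values were adjusted by Benjamini-Hochberg over the kept probes, with a threshold of 0.05. The test was two-sided. Where a named gene was below background on some or all arrays of its lower group, the fold is a bound: the mean of the bright group against the mean, in the other group, of the higher of the probe's own value and the lowest signal among detected probes of that array.

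Probes were named from the platform annotation given with the data. 34885 probes had 1 gene symbol, 18 had several and were not named, and 10378 are not named here. Entrez identifiers matched 34807 probes to RefSeq genes, and 19057 genes were named on the array. A gene stands for its kept probe with the highest mean level; where another kept probe differed in direction or call, this is stated. Named genes followed a rule fixed before the data were examined: every Tpm1 to Tpm4 probe; the 10 genes with the largest change in each direction among called genes whose groups did not overlap, filled up with the lowest unadjusted p where fewer passed; and in each list the 3 measured members with the lowest unadjusted p.

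27 gene lists were fixed before the data were examined and tested with camera at a preset correlation between genes of 0.01, for lists with at least 3 measured genes, with Benjamini-Hochberg adjustment over the lists. camera with an estimated correlation and fry were run beside it. Counts adjusted over the list alone use limma's p-values of the measured members.

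The steps were tested on simulated data: 5 simulations of the 23354 probes with 200 changed probes each, and lists shifted by 0.5 on the log2 scale. Of the calls, 5.93% were false. All 15 shifted lists were called and 0 of 120 others, with the preset and with the estimated correlation. Probes varied independently of each other in these simulations, so they do not test lists whose genes move together. On the real arrays the estimated correlation was 0.88 for fat pad expansion and 0.38 for unfolded protein response genes, but -0.01 for interferon response genes.

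Alternatives planned before the data were examined were no background correction, an offset of 50, scaling on the 75th percentile, the series matrix values on the log2 scale without normalization, no filter or stricter filters on dim probes, a trended and robust prior, array weights, each array left out in turn, an adjusted p under 0.10, a fold change of at least 1.5, the mean of all probes of a gene, an estimated correlation and fry. For lists the trended prior was run without its robust part, which camera lacks. The table called non-normalized, and a fit with the mean level of the epididymis and testis list as a covariate, were added after the data were seen. Other splits of the 9 mice into 5 and 4 were compared with the real one, 100 splits in all out of 126, the real one included. Correlations, exact permutation tests and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No mouse was left out of the comparisons, although all wild-type arrays and transgenic mice 152 and 147 carried some epididymal transcripts at wild-type levels, because leaving out all of these would have removed the wild-type group.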

Results

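RNA was measured on Illumina whole-genome mouse bead arrays in epididymal fat, the fat pad that lies against the epididymis, of 9 FVB/N mice. The mice were 3 months old and had been fasted for 14 to 16 h. 5 mice, labelled tg/tg, carried a transgene for Tm5NM1, a cytoskeletal tropomyosin that is a product of the Tpm3 gene. The other 4, labelled wt/wt, were wild type. Mice are named here by the submitters' numbers (165, 152, 147, 163 and 164 transgenic, 141, 142, 143 and 159 wild type), and each array stands for 1 mouse. Each array held 45281 probes, of which 22239 to 23313 were detected above background at a detection p under 0.05. The median signal lay between 142 and 192 per array before normalization. In wild-type mice 142, 143 and 159 it was 142 to 147, and in wild-type mouse 141 and the transgenic mice 169 to 192. No transgenic array lay in the dimmer set. Whether these arrays were processed apart is not given in the sources used here. Such an effect would largely coincide with genotype and was not tested. The tests used 23354 probes detected on at least 4 arrays, and these covered 12171 named genes. Pairs of arrays correlated with r between 0.903 and 0.990 over these probes. The number of arrays limits the precision of every comparison.

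The expression of Tpm3 was examined first, because it bears on the transgene. The brightest Tpm3 probe read 13.39 ± 0.27 (SD, n = 5) on the log2 scale in transgenic fat and 12.85 ± 0.34 (SD, n = 4) in wild-type fat. This was a log2 fold change of 0.54, with a 95% confidence interval of 0.10 to 0.98, and it did not pass the test over all probes (limma adjusted p = 0.452). Transgenic mice gave 13.40 (mouse 165), 13.83 (152), 13.39 (147), 13.09 (163) and 13.26 (164), and wild-type mice 13.07 (141), 13.21 (142), 12.62 (143) and 12.51 (159). The other Tpm3 probe detected on all 9 arrays differed by 0.26 (limma adjusted p = 0.817), and the remaining 4 Tpm3 probes were detected on at most 3 arrays and were not tested. Whether a Tpm3 probe lies in sequence that the transgene carries is not given in the sources used here, so the Tpm3 signal does not test the genotype labels. The value moved with the scaling: without normalization between arrays, where the median over all probes was itself 0.34 higher in transgenic mice, the difference was 0.88 with an adjusted p of 0.0361, and with array weights it was 0.30 with an adjusted p of 0.315.

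None of the other tropomyosin genes passed the test. Tpm1 differed by 0.14 (adjusted p = 0.867) and its dimmer tested probe by 0.11 (adjusted p = 0.893), and 1 further Tpm1 probe was not detected on any array. Tpm2 differed by 0.24 (adjusted p = 0.824), with 2 further probes not detected. Tpm4 differed by -0.06 at its brightest probe (adjusted p = 0.955), by -0.06 at the next (adjusted p = 0.970) and by 0.52 at the dimmest (adjusted p = 0.513). As a list, the 4 tropomyosin genes were not shifted against other genes (camera, adjusted p = 0.434), with 3 members higher and 1 lower and none past the threshold adjusted over the list alone.

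The comparison of all genes asked which genes differ between transgenic and wild-type fat. What fell in transgenic fat was a small set of genes, among them beta-defensins, cystatins and lipocalins; Lcn10 and Lcn9 belonged to the epididymis and testis list fixed beforehand. Epididymal genes of that list varied from mouse to mouse within each genotype, and in transgenic mouse 152 Gpx5 read 15.88, Adam7 15.99 and Lcn5 14.70, within or above the range of the wild-type mice. In transgenic mouse 147 they read 13.81, 11.99 and 10.01, with only Lcn5 inside that range. 16 probes of 13 named genes passed the test, all lower in transgenic mice, and none passed as higher (limma with Benjamini-Hochberg adjustment, threshold 0.05). All 16 probes were detected on every wild-type array, and 9 of them on no transgenic array. The beta-defensin Defb48, below background in 1 transgenic mouse, was at least 470-fold lower, at 6.16 ± 0.90 (SD, n = 5) in transgenic against 15.14 ± 0.94 (SD, n = 4) in wild-type fat (limma adjusted p = 0.000218). Defb25, another beta-defensin, was 139-fold lower (adjusted p = 0.000862). The cystatin family genes Cstdc2 and Cst12, each detected in 1 of the 5 transgenic mice, were at least 147-fold and at least 125-fold lower (adjusted p = 0.00103 for both).

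For genes below background on some or all transgenic arrays only a bound can be given, computed against the lowest signal detected on each array. Pate5, of the PATE family of small secreted proteins, was at least 228-fold lower (adjusted p = 0.000498). The predicted gene Gm3428 was at least 202-fold lower and the metalloprotease Adam28 at least 156-fold lower (adjusted p = 0.000498 for both). Adam28 passed at 3 probes, while a further probe differed by -2.24 and did not (adjusted p = 0.269). The transmembrane epididymal protein gene Teddm1a was at least 34.6-fold lower (adjusted p = 0.0126). Its relative Teddm2 was at least 141-fold lower (adjusted p = 0.0144) and the lipocalin Lcn10 at least 138-fold lower (adjusted p = 0.0360), detected in 2 and in 1 of the transgenic mice. The lipocalin Lcn9 was at least 22.9-fold lower (adjusted p = 0.0376). In wild-type fat, each called gene given here with a fold read higher in mice 141 and 143 than in mice 142 and 159. Pate5, for example, read 14.71 and 14.98 against 12.48 and 11.66. Since these genes moved together from mouse to mouse, their folds do not count as separate results. The other called genes, Rpl3l and Atp10b, fell outside the rule for named genes and were named after their values were seen.

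These counts depended on single mice. Without transgenic mouse 152 the test called 50 probes, 10 of them higher and 40 lower, and without wild-type mouse 142 it called 37, 3 of them higher. Without wild-type mouse 141 it called 2 higher and 10 lower, whereas without transgenic mouse 147, 163 or 164 it called 9. With array weights, which gave the least weight to mice 159 and 152, it called 170 probes higher and 183 lower.

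No gene passed as higher in transgenic fat, and the lowest adjusted p among the higher genes was 0.0504. At an unadjusted p under 0.05, limma gave 1413 probes higher and 793 lower, 2206 in all, against 1168 by chance. The groups did not overlap at 749 probes, 3.21% of those tested, against 1.59% by chance. The gene nearest to the threshold was Mpp4, a membrane scaffold protein, with a log2 fold change of 1.03; it was not detected in wild-type fat, which makes the difference at least 1.25-fold (limma adjusted p = 0.0504). Mpp4 passed without transgenic mouse 152 (adjusted p = 0.0238) and without wild-type mouse 142 (0.0492). Over its 18 alternatives the adjusted p ranged from 0.00337 to 0.305. C1qtnf9, a secreted relative of adiponectin, read 11.68 ± 0.07 (SD, n = 5) against 10.71 ± 0.28 (SD, n = 4), a log2 fold change of 0.98 (limma adjusted p = 0.0639). It passed without background correction (adjusted p = 0.0400), with an offset of 50 (adjusted p = 0.0454) and with a prior made both trended and robust (adjusted p = 0.0348). Tnfrsf14, a receptor on lymphocytes, differed by 0.98 (adjusted p = 0.0843), and it passed without transgenic mouse 152 (adjusted p = 0.0290). Also named by the rule, and not past the threshold, were Pou2f2, a lymphocyte transcription factor, at least 1.46-fold (adjusted p = 0.108), Plppr3 (at least 1.63-fold), Ndrg2 (log2 fold change 0.69), Fam155a (at least 1.05-fold), P2rx7, an ATP-gated ion channel (log2 fold change 0.75), Agtpbp1 (log2 fold change 0.63) and Treml2 (at least 1.59-fold), with adjusted p between 0.127 and 0.205 for these last 6. All of these genes were higher in every transgenic mouse than in every wild-type mouse. They were picked by the lowest p, which favours such a separation, so it adds no support.

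**Figure D1:**
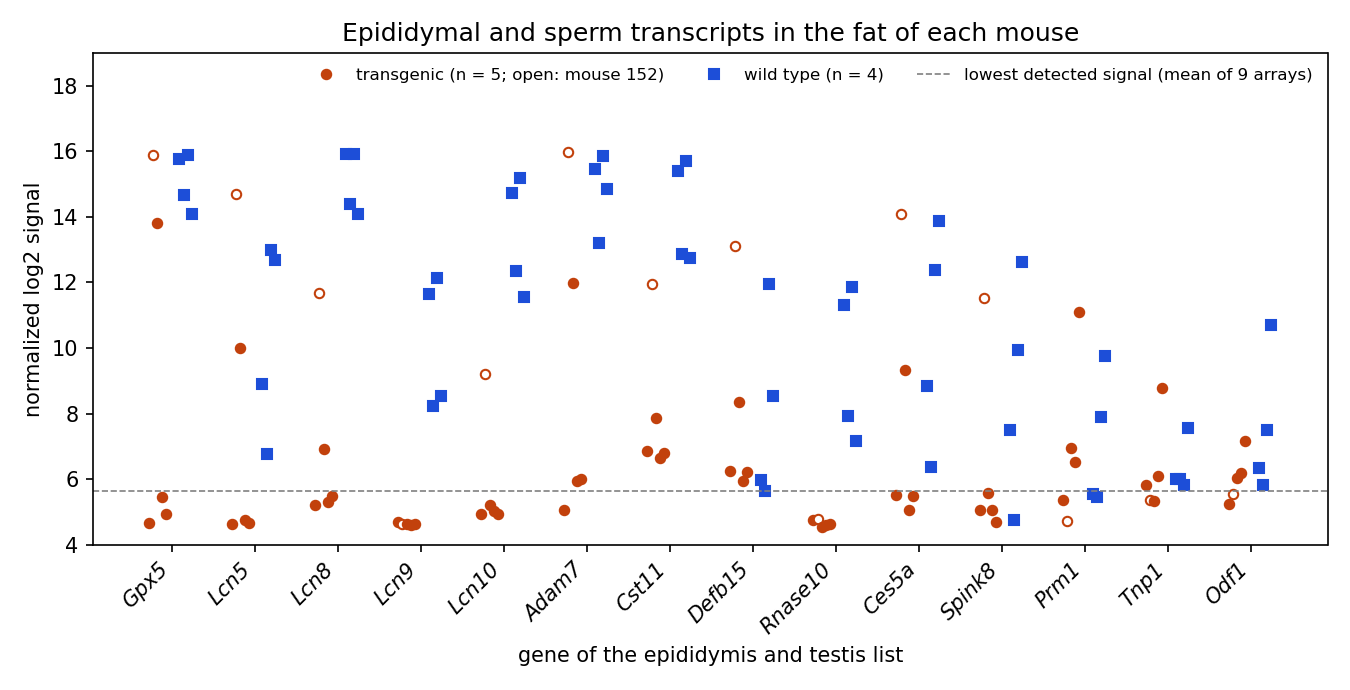
Normalized log2 signal of the 14 measured genes of the epididymis and testis list, 1 point per mouse, orange circles for 5 transgenic (mouse 152 open) and blue squares for 4 wild-type mice, with the lowest detected signal dashed. Gpx5 lay between 14.08 and 15.89 in all wild-type mice, at 15.88 in transgenic mouse 152 and at 13.81 in transgenic mouse 147. In transgenic mice 165, 163 and 164 it lay between 4.67 and 5.45.

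Gene lists fixed before the data were examined were then compared with all other genes by camera, with adjustment over 27 lists. 5 lists passed, 4 lower and 1 higher in transgenic fat, and 26 of the lists held no gene that passed over all probes. With a correlation estimated for each list in place of the preset 0.01, none of the 5 calls held. fry, which asks whether a list's genes move on balance one way, called none. Its mixed form, which asks for change in either direction, called 1 list, epididymis and testis.

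Genes of the epididymis and testis list fell furthest. All 14 measured genes, of 17 fixed, were lower, with a median log2 fold change of -3.75 (camera adjusted p = 4.14e-10; p = 0.0160 and adjusted p = 0.344 with an estimated correlation). 2 of them, Lcn10 and Lcn9, passed over all probes, and 7 were lower adjusted over the list alone. Lcn8, another lipocalin, read 6.91 ± 2.75 (SD, n = 5) against 15.08 ± 0.97 (SD, n = 4; limma adjusted p = 0.0595). The signal varied within each genotype. The list mean was 5.29 in transgenic mouse 165, 5.51 in 163, 6.11 in 164, 7.61 in 147 and 10.22 in 152, and 8.89 in wild-type mouse 142, 10.67 in 141, 11.34 in 159 and 12.22 in 143. This epididymal level is set beside those lists below that were called, lay near the threshold or passed in alternatives with a mouse left out, and beside circadian clock genes, as a correlation of list means across the 9 mice with exact permutation p-values, in a family of 26 relations of which none passed Benjamini-Hochberg adjustment at 0.05. In each case r was computed again without mice 165 and 163, the 2 farthest from the median level, and on deviations from the genotype means. Mouse 152 was kept in these checks, so they cannot show whether a relation rests on that mouse. The level includes the sperm genes Prm1, Tnp1 and Odf1; without them it ran from 5.24 in mouse 165 to 13.62 in mouse 143, with 5.32 in mouse 164, 11.95 in 141 and 11.89 in 159. This changed r by at most 0.09 for any list, and again none of the relations passed.

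Genes of the mesothelial list, chosen for the lining of the fat pad, were lower at all 10 of 10 measured members, of 12 fixed (median -0.82, camera adjusted p = 0.000784; p = 0.0382 and adjusted p = 0.344 with an estimated correlation). The list includes the keratins Krt7, Krt8, Krt18 and Krt19, and whether its signals came from the lining was not tested. None passed adjusted over the list alone. The uroplakin Upk1b read 8.58 ± 1.74 (SD, n = 5) against 11.05 ± 0.95 (SD, n = 4), the keratin Krt7 differed by -0.65 and the membrane glycoprotein Gpm6a by -0.81 (limma adjusted p = 0.418, 0.546 and 0.610). The list mean correlated with the epididymal level with r = 0.51 (exact permutation p = 0.163, adjusted 0.250) and rho = 0.43 (p = 0.250, adjusted 0.389), r = 0.60 without the farthest 2 mice and -0.02 within genotypes.

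Genes of the unfolded protein response were lower at 12 of 13 measured members, of 14 fixed (median -0.26, camera adjusted p = 0.00176; p = 0.139 and adjusted p = 0.821 with an estimated correlation), with none past adjusted over the list alone. The chaperone Dnajb9 differed by -0.90 (limma adjusted p = 0.354), the stress-induced enzyme Chac1 by -0.56 (0.586) and the chaperone-associated Sdf2l1 by -0.94 (0.606). The call was lost without wild-type mouse 159 (adjusted p = 0.0619). The list mean correlated with the epididymal level with r = 0.84 (exact permutation p = 0.00663, adjusted 0.0726) and rho = 0.77 (p = 0.0214, adjusted 0.0947), r = 0.82 without the farthest 2 mice and 0.77 within genotypes.

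Fat pad expansion genes, which vary with the growth of the fat pad, were the only list called higher. All 9 of 9 measured members, of 10 fixed, were higher (median 0.57, camera adjusted p = 0.0159; p = 0.301 and adjusted p = 0.821 with an estimated correlation), with none past adjusted over the list alone. The caveolar coat gene Cavin1 (Ptrf) differed by 0.57 (limma adjusted p = 0.530), the natriuretic peptide receptor gene Npr3 by 0.90 (0.538) and Bmp3 by 1.47 (0.545). The call was lost without transgenic mouse 165 (adjusted p = 0.104), wild-type mouse 143 (0.126) or wild-type mouse 159 (0.383), with array weights (0.251) and without normalization between arrays (0.584). The list mean correlated with the epididymal level with r = -0.72 (exact permutation p = 0.0262, adjusted 0.0973) and rho = -0.78 (p = 0.0172, adjusted 0.0947), r = -0.71 without the farthest 2 mice and -0.64 within genotypes.

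Genes of the fasting and glucocorticoid response were lower at 11 of 13 measured members, of 13 fixed (median -0.23, camera adjusted p = 0.0295; p = 0.216 and adjusted p = 0.821 with an estimated correlation), with none past adjusted over the list alone. The kinase Sgk1 differed by -0.77 (limma adjusted p = 0.450), the cell cycle inhibitor Cdkn1a by -0.93 (0.551) and the glucocorticoid receptor cochaperone Fkbp5 by -0.58 (0.616). The call was lost without transgenic mouse 165 (adjusted p = 0.104) or 152 (0.0582), without wild-type mouse 142 (0.0758) or 159 (0.383), and with array weights (0.530). The list mean correlated with the epididymal level with r = 0.35 (exact permutation p = 0.404, adjusted 0.456) and rho = 0.27 (p = 0.493, adjusted 0.558), r = 0.26 without the farthest 2 mice and -0.08 within genotypes.

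**Figure D2:**
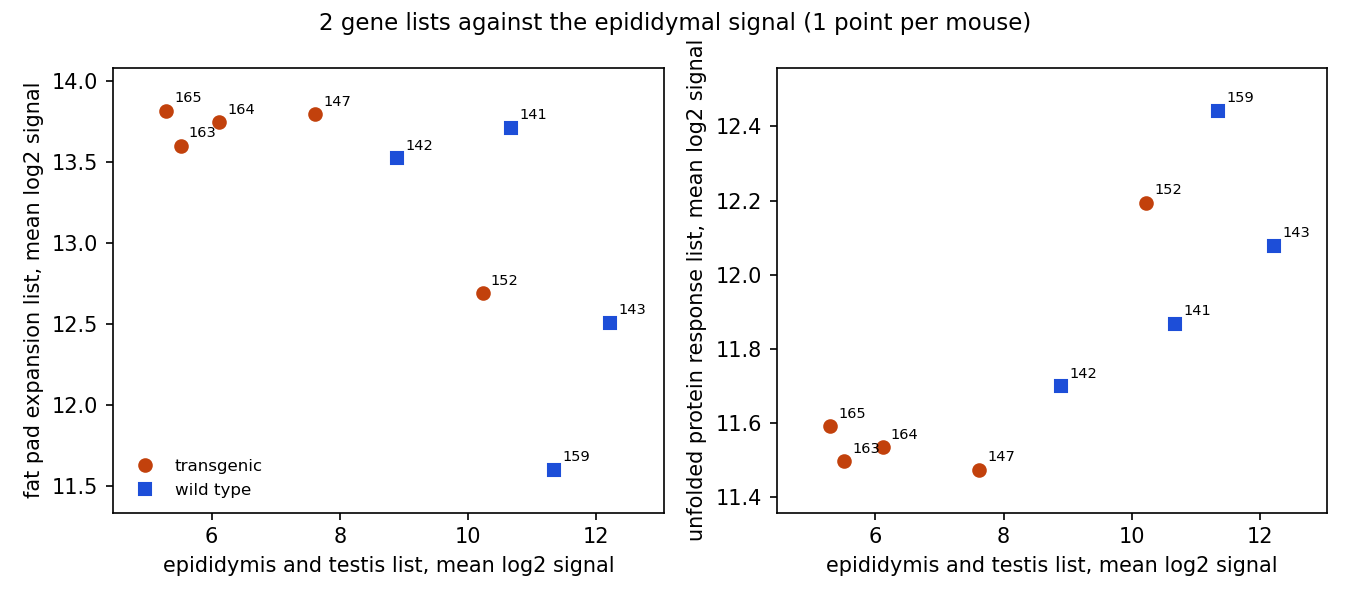
Mean log2 signal of the fat pad expansion list (left) and the unfolded protein response list (right) against that of the epididymis and testis list, 1 point per mouse with its number, orange circles transgenic and blue squares wild type. The expansion mean was lowest, at 11.60, in wild-type mouse 159, and transgenic mouse 152 lay at 12.69, below the other transgenic mice.

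2 lists missed the threshold by little, both with higher values in transgenic fat. Endothelial genes were higher at all 13 of 13 measured members, of 14 fixed (median 0.20, camera adjusted p = 0.0517; p = 0.448 and adjusted p = 0.863 with an estimated correlation). The list passed as higher in 9 of 23 alternatives and as lower in 1, that with the epididymal level as a covariate (adjusted p = 0.00311), with adjusted p from 6.84e-06 to 0.863 over all of them. It passed without transgenic mouse 152 (6.84e-06), wild-type mouse 142 (0.0314) or wild-type mouse 159 (0.0220). Its named members were Ramp2 (0.42), Tie1 (0.61) and Cldn5 (0.50), with limma adjusted p between 0.458 and 0.567. Its mean correlated with the epididymal level with r = -0.78 (exact permutation p = 0.0151, adjusted 0.0726) and rho = -0.75 (p = 0.0255, adjusted 0.0947), r = -0.68 without the farthest 2 mice and -0.83 within genotypes. Interferon response genes were higher at 8 of 10 measured members, of 16 fixed (median 0.21, camera adjusted p = 0.0527; p = 0.0368 and adjusted p = 0.344 with an estimated correlation). The list passed as higher in 7 of 23 alternatives, among them those without transgenic mouse 147 (adjusted p = 0.0201), transgenic mouse 163 (0.0422) or wild-type mouse 159 (0.0229), with adjusted p from 0.0201 to 0.400 over all of them. 2 of them passed as higher adjusted over the list alone. The antiviral Rsad2 read 9.62 ± 0.24 (SD, n = 5) against 9.07 ± 0.07 (SD, n = 4; limma adjusted p = 0.348 over all probes) and Ifit3 9.46 ± 0.15 (SD, n = 5) against 8.83 ± 0.33 (SD, n = 4; adjusted p = 0.348), and Ifit2 differed by 0.37 (adjusted p = 0.581). The mean of the list lay between 9.06 and 9.35 in the transgenic mice and lower in every wild-type mouse, with a gap of 0.05 between the genotypes, and it correlated with the epididymal level with r = -0.79 (exact permutation p = 0.0167, adjusted 0.0726) and rho = -0.82 (p = 0.0108, adjusted 0.0947), r = -0.72 without the farthest 2 mice and -0.43 within genotypes.

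Circadian clock genes were split, with 6 of 12 measured members higher and 6 lower, of 15 fixed (camera adjusted p = 0.332). 3 members passed as higher adjusted over the list alone, namely the repressor Cry2, by 0.57, and the transcription factors Tef, by 0.53, and Nr1d2, by 0.55 (limma adjusted p = 0.346, 0.350 and 0.366 over all probes). A dimmer probe of Nr1d2 differed by -0.22 (adjusted p = 0.848). The list mean correlated with the epididymal level with r = -0.81 (exact permutation p = 0.00890, adjusted 0.0726) and rho = -0.75 (p = 0.0255, adjusted 0.0947), r = -0.92 without the farthest 2 mice and -0.64 within genotypes. In none of the lists that follow did a gene pass adjusted over the list alone, and camera's adjusted p is given for each.

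Lists of fat cell function did not pass. Adipocyte identity genes were higher at 11 of 19 measured members (adjusted p = 0.916), with Fabp4, a fatty acid carrier, at 1.27 (limma adjusted p = 0.369), the lipase gene Pnpla2 at -0.32 (0.638) and leptin, Lep, at 0.52 (0.672). Fatty acid and triglyceride synthesis genes were lower at 11 of 19 (adjusted p = 0.437), with the regulator Mlxipl at 0.45 (limma adjusted p = 0.481), Acacb at -0.60 (0.525) and the desaturase Fads2 at -0.93 (0.626). Fads2 read 10.01 in transgenic mouse 152, 6.73 to 8.33 in the other transgenic mice and 8.56 to 9.72 in wild-type mice. Its relation with the epididymal level was not tested. Cholesterol synthesis genes were lower at 10 of 14 (adjusted p = 0.124), with Stard4 at 0.49 (limma adjusted p = 0.410), Cyp51 at -0.61 (0.557) and Idi1 at least 1.04-fold lower (0.592). The cholesterol synthesis list passed without wild-type mouse 159 (adjusted p = 0.00167), with array weights (0.00308) and without normalization between arrays (0.0118), where fatty acid and triglyceride synthesis passed too (0.0118); neither passed with an estimated correlation (0.821 and 0.863). The cholesterol synthesis mean correlated with the epididymal level with r = 0.46 (exact permutation p = 0.215, adjusted 0.294), r = 0.45 without the farthest 2 mice and 0.33 within genotypes. Lipolysis genes were higher at 6 of 10 (adjusted p = 0.916); beside Pnpla2 the named members were Abhd5, at -0.24, and G0s2, at 0.36. The sign of the lipolysis test was down while the median and mean were above 0. Fatty acid oxidation genes were higher at 9 of 17 (adjusted p = 0.976), with Cpt1a at least 1.08-fold higher, Ehhadh at -0.94 and Acads at 0.34, where another Acads probe differed by -0.23; here too the test pointed down while median and mean were above 0. With the epididymal level as a covariate adipocyte identity (adjusted p = 0.000294), lipolysis (0.00626) and fatty acid oxidation (0.00311) passed as lower; with an estimated correlation and no covariate the adjusted p was 0.991 for each of the 3. The covariate is confounded with genotype, with a mean of 6.95 in transgenic and 10.78 in wild-type mice.

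Genes of glucose uptake and insulin signalling were higher at 11 of 21 measured members (adjusted p = 0.700, with the test and mean down and the median above 0), with Igf1r at -0.61 (limma adjusted p = 0.531), Pik3ca at 0.34 (0.643) and Pik3r1 at 0.35 (0.672). Oxidative phosphorylation genes were higher at 22 of 24 (median 0.07, adjusted p = 0.149, or 0.0442 without the filter on dim probes, the only 1 of 23 alternatives in which the list passed), with Ndufb8 at 0.28 (limma adjusted p = 0.525), Uqcrc1 at 0.21 (0.643) and Cox6c at 0.20 (0.643). Brown and beige adipocyte genes were higher at 7 of 8 (adjusted p = 0.614), with Ebf2 at 0.36, Prdm16 at 0.37 and Tbx1 at least 1.12-fold lower. Actin filament and actomyosin genes, the partners of tropomyosin, were higher at 18 of 26 (median 0.06, adjusted p = 0.714), with filamin A, Flna, at 0.33 (limma adjusted p = 0.513), Cald1 at 0.33 (0.599), where another probe differed by -0.04, and Tagln2 at 0.17 (0.683).

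Lists of immune and stromal cells did not pass either. Macrophage genes were higher at 15 of 20 measured members (adjusted p = 0.700), with Cd14 at -0.69, Clec7a at 0.55 and Aif1 at 0.45. Genes of inflammatory cytokines and the acute phase were higher at 8 of 12 (adjusted p = 0.700), with haptoglobin, Hp, at 0.63 (limma adjusted p = 0.402), Nos2 at least 1.37-fold higher (0.587) and Lcn2 at -1.17 (0.609). Lcn2 read 15.35 in transgenic mouse 152, 11.89 to 14.05 in the other transgenic mice and 13.62 to 15.89 in wild-type mice. Its relation with the epididymal level was not tested. T and B lymphocyte genes were higher at 9 of 11 (median 0.61, adjusted p = 0.0680), with Ccr7 at least 1.04-fold higher, Ltb at least 1.48-fold higher, both below background in part of the wild-type mice, and Cd3g at 0.71; the list passed without transgenic mouse 152 (adjusted p = 0.0190), without transgenic mouse 163 (0.0128) and without wild-type mouse 159 (0.0229), in 5 of 23 alternatives in all, but not with an estimated correlation (p = 0.311, adjusted p = 0.821). Extracellular matrix genes were higher at 16 of 22 (adjusted p = 0.332), with Ccn2 (Ctgf) at -0.54 (limma adjusted p = 0.354), Col1a2 at 0.54 (0.486) and Col1a1 at 0.52 (0.517), and the list passed without transgenic mouse 152 (0.0183) but not with an estimated correlation (adjusted p = 0.903). With the epididymal level as a covariate, which is confounded with genotype, the extracellular matrix and macrophage lists passed in the other direction, as lower (adjusted p = 0.000294 for both); for macrophage genes the adjusted p was 0.955 with an estimated correlation and no covariate. Across the 9 mice the extracellular matrix mean correlated with the epididymal level with r = -0.81 (exact permutation p = 0.0105, adjusted 0.0726; -0.74 without the farthest 2 mice and -0.97 within genotypes) and the T and B lymphocyte mean with r = -0.69 (exact permutation p = 0.0350, adjusted 0.114; -0.74 and -0.57). Preadipocyte and stromal genes were higher at 5 of 10 (adjusted p = 0.714), with Pdgfra at -0.38, Pdgfrb at 0.41 and Thy1 at 0.36.

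Of the remaining lists, cell cycle genes were higher at 10 of 13 measured members (median 0.27, adjusted p = 0.124), with the topoisomerase Top2a at 1.11 (limma adjusted p = 0.346), Cdk1 at 0.76 (0.517) and Mcm3 at 0.38 (0.652), and the list passed without wild-type mouse 141 (0.0285) but not with an estimated correlation (adjusted p = 0.821). Its mean correlated with the epididymal level with r = -0.77 (exact permutation p = 0.0124, adjusted 0.0726), r = -0.70 without the farthest 2 mice and -0.58 within genotypes. Immediate early genes were higher at 6 of 12 and lower at 6 (adjusted p = 0.604, with the test and mean down and the median above 0), with Ier3 at -0.78, Egr2 at -2.79 and Jun at 0.27. Egr2 read 13.10 in mouse 152, which had the highest epididymal level of the transgenic mice. It read 7.03 to 9.06 in the other transgenic mice and 10.36 to 13.27 in wild-type mice. A relation of Egr2 with the epididymal level was not tested. Skeletal muscle genes were higher at 5 of 7 (adjusted p = 0.700, with the test and mean down and the median above 0), with Acta1 at -0.65, Tnni2 at 0.39 and Mb at least 1.30-fold lower, where another Mb probe differed by 0.07. Red blood cell genes were higher at 4 of 4 (adjusted p = 0.695), with Hbb-b2 at 0.50, Slc4a1 at 0.39 and Hba-a1 at 0.01.

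**Figure D3:**
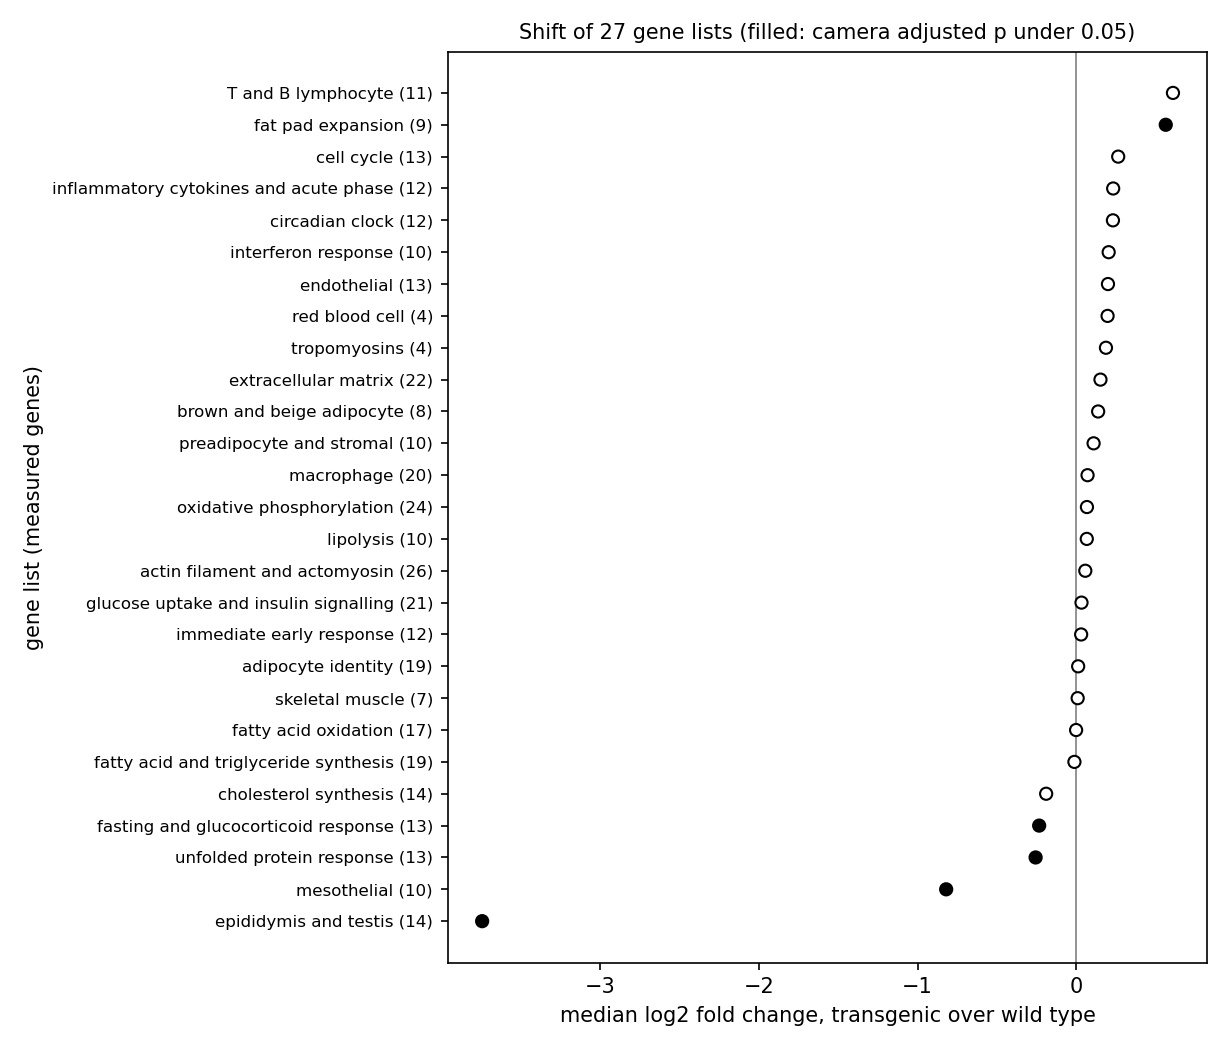
Median log2 fold change, transgenic over wild type, of the measured genes of each of 27 lists (number of measured genes in parentheses), filled where camera's adjusted p was under 0.05 and open otherwise. The epididymis and testis list stands at -3.75, while the other 26 medians lie between -0.82 and 0.61.

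On data simulated from these arrays, the same test recovered 50% of probes changed by 1 on the log2 scale and 96% of those changed by 3. Smaller changes in single genes, such as those of most list members above, were therefore open to being missed at this number of mice. The simulations changed 200 probes, against 16 called on the real arrays. More changed probes loosen the adjusted threshold, so the share recovered on the real arrays can be lower.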

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

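All tests of explanations in this part were chosen after the results were seen. Among 252 groups checked, being 99 named genes and 27 list means in each genotype, 30 had a mouse whose gap to its nearest neighbour filled more of the group's range than Dixon's 95% value allows, where chance gives about 1 in 20 groups, or 13. Transgenic mouse 152 was the mouse set apart in 17 of the 30, and wild-type mouse 159 in 6. The groups are not independent, since the same mice recur and many named genes are members of the lists. A single deviating mouse can thus be counted many times, and the excess over 13 is not a test.

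Mouse 152 was higher than the other transgenic mice for Lcn10 (9.20, gap 0.932 of the range), Lcn8 (11.67, 0.735), Teddm2 (8.59, 0.775), Fkbp5 (0.794) and the unfolded protein response list (12.19, 0.839). It was lower for Lep (14.49, 0.901), Abhd5 (11.48, 0.748), Cavin1 (13.28, 0.845), Npr3 (13.29, 0.797), Bmp3 (9.82, 0.804), Nos2 (5.43, 0.750) and Pdgfrb (8.95, 0.879). It was also lower for the lists of fat pad expansion (12.69, 0.807), endothelial (10.89, 0.786), extracellular matrix (11.32, 0.750), red blood cell (10.43, 0.763) and lipolysis (11.22, 0.720) genes.

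Wild-type mouse 159 was lower than the other wild-type mice for G0s2 (11.08, 0.900), Acads (9.95, 0.842) and Pik3r1 (12.71, 0.868). It was higher for Ccn2 (13.52, 0.834), Dnajb9 (13.54, 0.882) and the T and B lymphocyte list (7.16, 0.838). Wild-type mouse 142 was lower for Tpm2 (9.93, 0.834) and higher for Tagln2 (13.02, 0.854), and wild-type mouse 143 was lower for Pik3ca (8.52, 0.846) and Pdgfrb (8.65, 0.893). Among transgenic mice, mouse 147 was higher for Cst12 (5.74, 0.849), mouse 163 higher for Agtpbp1 (7.61, 0.912) and mouse 165 lower for Prdm16 (6.21, 0.735).

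The lower level of epididymal transcripts in transgenic fat may come from epididymal tissue carried over with the fat pad in some mice. The mean of the epididymis and testis list ranged over 4.93 within the transgenic and 3.33 within the wild-type mice on the log2 scale, where the smaller of the 2 ranges was at most 1.13 for any other list. An effect of the transgene on the whole list cannot be told apart from a difference in the tissue taken. Of the 9 epididymal genes whose lowest wild-type mouse was above background, 4 were detected at or above that mouse in transgenic mouse 152, 2 in mouse 147 and 0 in the others, so that only 1 transgenic mouse reached 3 genes. For the 16 called probes, an effect of the transgene likewise cannot be told apart from a difference in the tissue taken, since a transgenic mouse reached the lowest wild-type mouse on 0 of them and they were picked by that comparison. Chance is argued against for the number of called probes, with 3 of 100 splits, the real one among them, giving at least the real 16. However, the highest other split gave 465, and it set the mice with the highest epididymal levels (152, 141, 143 and 159) against the rest. Another split gave 142, and it set the mice with the lowest levels (165, 147, 163 and 164) against the rest. Both point to this structure of the samples. Chance cannot be excluded for the number of called lists, where 67 of 100 splits, the real one among them, gave at least 5 and the highest other gave 14.

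Dilution of fat RNA by epididymal RNA may lower fat pad expansion genes, in which case all fat cell transcripts would fall alike. As the whole cause of the difference between genotypes it is argued against by 14 adipocyte identity genes, whose median difference was 0.0542 (SD over genes 0.38), against 0.57 for the expansion list, with 13 of the 14 below that value. The expansion list minus these genes differed by 0.56 between genotypes (exact permutation p = 0.0476 over all splits). This rests on wild-type mice 143 (1.25) and 159 (0.76), since mice 141 (2.04) and 142 (1.90) lay among the transgenic mice (1.84 to 2.17). Without mouse 159 the value was 0.32 (exact permutation p = 0.107), and the p was under 0.05 in only 1 of the 9 sets with 1 mouse left out. The median of the 14 adipocyte genes ran from -0.17 (without mouse 159) to 0.20 (without mouse 152). Dilution as a part of the cause, and across mice, stays open. Within genotypes the mean of the full adipocyte identity list fell with the epididymal level (r = -0.80), as did lipolysis (-0.79) and fatty acid oxidation (-0.78). Among transgenic mice, mouse 152 had the highest epididymal level and the lowest mean of each of these lists, and r was not computed without it. The lipolysis list shares Lipe, Pnpla2, Plin1 and Aqp7 with the adipocyte identity list, so these relations are not separate. Over all 9 mice r was -0.63 for adipocyte identity (exact permutation p = 0.0711, adjusted 0.185). The 14 adipocyte genes were chosen below a mean level of 15 and without Lep. The difference between the expansion list and these genes fell with the epididymal level by Pearson's r (-0.65, exact permutation p = 0.0470) but not by Spearman's rho (-0.52, exact permutation p = 0.162). It gave r = -0.71 without mice 165 and 163 and -0.36 within genotypes, and -0.59 (exact permutation p = 0.0932) against the level without sperm genes, which leaves open whether dilution accounts for the relation with the epididymal level. An effect of the transgene on these genes cannot be told apart from the epididymal level, since with that level as a covariate the list turned lower and was not called (adjusted p = 0.428). The size of the fat pads was not analysed here.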

How the results depend on the processing

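The alternatives on the table called non-normalized and with the epididymal level as a covariate were chosen after seeing the data; all others were planned. The 16 called probes, all lower, became 9 without the filter on dim probes, 1 (Defb25) when detection on all arrays was required, and 30, 4 higher and 26 lower, at an adjusted p under 0.10. Array weights gave 353, 170 higher and 183 lower. The log2 series matrix values without normalization gave 4910, 4850 higher and 60 lower, with a median over all probes of 0.34; that shift of all probes is what normalization removes. In each of the last 3 settings all 16 were among the calls. The epididymal covariate gave 10, 5 higher (Lcn12, Pate6, Defb35, C4bp and Defb19) and 5 lower, with 5 of the 16 among them. 1 probe was higher without background correction, with an offset of 50 and with a prior both trended and robust (C1qtnf9 in each), with 75th percentile scaling (Tenm4), and on the table called non-normalized (Parp14), where 21 passed and included all 16. With 1 mouse left out the total ranged from 9 to 50, the higher probes from 0 to 10 and the lower from 9 to 40, with mice 152, 142, 141, 147, 163, 164 and 159 each moving a count by over 1.5 times; without mouse 152, the higher named genes were Mpp4, Tenm4, Tnfrsf14, Pou2f2, Dock2, Hip1 and Unc45bos. The cause of the other differences was not tested.

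The 5 called lists became 8 without the filter, 0 with an estimated correlation and 0 with fry, and 3 to 7 with 1 mouse left out, lowest without transgenic mouse 165. 6 lists passed with the covariate, all as lower and none of them among the 5; the epididymis and testis list was left out of that test. There the fat pad expansion list (adjusted p = 0.428, range over its alternatives 0.000238 to 0.821) and the unfolded protein response list (0.431, range 7.03e-06 to 0.821) turned the other way; the cause was not tested. Without wild-type mouse 159 only 2 of the 5 called lists passed. The Tpm3 difference of 0.54 was 0.88 without normalization (adjusted p = 0.0361, range over all alternatives 0.0361 to 0.731), 0.30 with array weights, and 0.42 to 0.66 with 1 mouse left out. No paired analysis was possible because the 2 genotypes share no mouse number, and a slide block was not run because no array barcodes were used here. Signal over background limits the genes below background in 1 group to bounds, and signals near the top of the scale, 16.03 on every array, can hide differences.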

Other observations

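All tests in this part were chosen after the results were seen. Interferon response was the only 1 of the 27 lists whose mean separated the genotypes completely, by a gap of 0.05 above the highest wild-type mouse. Chance separates 1.59% of lists, or 0.429 of the 27, so that 1 list is near what chance gives.

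Epididymal genes differed in which of them were present. Transgenic mouse 152 held Gpx5 at 15.88, Adam7 at 15.99, Lcn5 at 14.70 and Ces5a at 14.10, as high as or higher than nearly all wild-type mice, while Lcn9 (4.62) and Rnase10 (4.77) were below the lowest detected signal. In wild-type mouse 141, Lcn9 read 11.64 and Rnase10 11.33, with Lcn5 at 8.89 and Ces5a at 8.84.

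Sperm transcripts followed another pattern than epididymal ones. The protamine gene Prm1 read 11.11 and Tnp1 8.79 in transgenic mouse 164, whose Gpx5 was at 4.92, and Prm1 read 9.76 in wild-type mouse 159 and 7.90 in wild-type mouse 143. A hypothesis is that the sample of mouse 164 may hold sperm or spermatid RNA. Of 14 further sperm and spermatid genes, listed before this test, 12 were on the array, 10 were detected in mouse 164, and 8 were higher there than in each of the other 4 transgenic mice. The sperm lactate dehydrogenase Ldhc was at 9.08 and the testis antizyme Oaz3 at 7.60, but the median gene was 0.99 higher than the mean of the other transgenic mice, just under the difference of 1 set for the hypothesis, which leaves it open. In wild-type mouse 159 these genes were higher still at Smcp (10.09), Oaz3 (9.37) and Pgk2 (8.38).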
